A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

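The deposited data are 2 tables of raw counts, 1 with the 6 libraries of WT_H2AZ and H2AZ_4KR and 1 with the 6 libraries of WT_Ino80 and Ino80_K929R. Each value is a count of fragments (read pairs) per gene, per the file headers, and was used without further normalization by the submitters. According to the submitters' processing notes, reads were aligned with Bowtie 0.12.2 to the sacCer3 genome. According to the file headers, fragments over exons were counted with featureCounts 2.0.1, without regard to strand and without reads that mapped to several places or overlapped several genes. Values of paralogs, overlapping genes and antisense pairs are therefore uncertain. Most gene models hold no UTRs, so their lengths are coding lengths. Both tables list the same 7127 genes. Of these, 6047 IDs matched a locus tag of the R64 reference table, 6038 of them with the same start and end, and the other 1080 IDs were kept without a reference name, apart from snoRNA and tRNA genes recognised by their names.

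Each mutant was compared with its own wild type in a fit of 6 libraries with edgeR 4.0.16 in R 4.3.3 (filterByExpr with a minimum count of 10, TMM factors, quasi-likelihood F test). A gene was called changed at a Benjamini-Hochberg adjusted p below 0.05 and a fold change over 1.5, the thresholds that the series states. The difference between the mutant effects and the difference between the wild types were tested as contrasts in 1 fit of all 12 libraries. Every adjusted p of a gene is from edgeR unless DESeq2 is named. These p-values measure the spread between the samples, and the labels do not say whether replicates came from separate cultures. Replicate numbers were not used to pair samples. CPM are fragments of a gene divided by all counted fragments of the library, on edgeR's CPM scale, and means are given with the SD of 3 libraries. A count of 0 allows up to 3 fragments per library, a floor that covers counting error only.

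Gene lists were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 43 lists tested of the 44 written, and again with an estimated correlation and with fry. Genes within 20 kb of a chromosome end formed 1 of these lists, and their share of changed genes was compared with that of other genes by Fisher's exact test, two-sided. Members were counted as changed over all genes tested and, separately, adjusted over the list alone. After list results had first been seen, names were also matched through commas and synonyms of the reference table, which added 7 members in 7 lists. Without them 18 lists in place of 20 passed in H2AZ_4KR, with adjusted p = 0.0501 for the core histones and 0.0522 for the phosphate regulon, and 11 passed both ways in Ino80_K929R. CRS5 and FLO8 matched no gene ID.

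The groups, tests, thresholds, gene lists, other settings to try and the rule for naming genes were set before the data were examined. That rule took the gene carrying the mutation, the 10 highest and the 10 lowest log2 fold changes among changed genes with a mean of at least 10 CPM and no overlap between the groups, up to 4 members with the smallest adjusted p of each list that passed, and the auxotrophic marker genes. Where fewer than 10 genes qualified, it added the 10 genes with the smallest p. For the difference between the mutants it took the 5 highest and the 5 lowest. Other genes named were chosen after their values were seen. The lists of Leu3 target genes, of snoRNA and snRNA genes and of tRNA genes, an offset that removed the trend of log CPM with gene length from each library (loess, span 0.5), the odds ratio near telomeres under other settings, and the relation of both effects with single libraries left out were chosen after seeing the data.

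The other settings tried were DESeq2 1.42.0, limma-voom, RLE factors, scaling by total counts, no filter on low counts, a replicate block, 1 fit of all 12 libraries, glmTreat at 1.5-fold, no fold limit, a fold over 2, other telomere distances (10, 30 and 50 kb) and leaving out each library in turn. Counts simulated from these libraries were called at an adjusted p below 0.05 without the fold limit, so they do not give the recovery of the full rule. The H2AZ table gave calls for 29 of 50 genes changed 1.5-fold, 49 of 50 changed 2-fold and 50 of 50 changed 4-fold, with 18 of 5891 unchanged genes called. The Ino80 table gave calls for 3, 14 and 50 of 50 at these sizes, with 2 of 5934 unchanged genes called.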

Results

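RNA was sequenced from budding yeast of the BY4741 background, cultured in the rich glucose medium YPD and collected in mid-log growth without treatment. The 12 libraries form 4 groups of 3. H2AZ_4KR carries arginine in place of 4 lysines of the histone variant H2A.Z, as its name states, and was set against WT_H2AZ. Ino80_K929R carries a substitution in Ino80, the ATPase of the INO80 chromatin remodelling complex, and was set against WT_Ino80. The series asks how each substitution alters RNA levels across the genome. Counted fragments came to 17454204, 18957785 and 17655925 in WT_H2AZ replicates 1, 2 and 3, and to 19235586, 17253140 and 17417376 in H2AZ_4KR. They came to 17303402, 18700339 and 18408810 in WT_Ino80, and to 20164258, 19642228 and 20000158 in Ino80_K929R. TDH3, a glycolytic gene, had the most fragments in every library, at 2.06% to 3.52% of the total.

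HTZ1 (YOL012C), which encodes H2A.Z, stood at 387 ± 62.3 CPM (SD, n = 3) in H2AZ_4KR and at 95.9 ± 2.88 CPM (SD, n = 3) in WT_H2AZ, and the fold change fitted by edgeR after TMM scaling was 4.45. INO80 (YGL150C) stood at 1200 ± 150 CPM (SD, n = 3) in Ino80_K929R and at 150 ± 24.4 CPM (SD, n = 3) in WT_Ino80. The labels do not say whether the mutant alleles are on plasmids or under other promoters. Each higher level goes with its substitution in the same libraries, so level and substitution cannot be told apart as sources of other changes. Both genes lie on sacCer3, HTZ1 on chromosome XV from 303579 to 303983 and INO80 on chromosome VII from 221104 to 225573. In the other table HTZ1 stood at 142 ± 1.23 CPM in WT_Ino80 and 134 ± 11.8 CPM in Ino80_K929R (SD, n = 3), and INO80 stood at 172 ± 11.6 CPM in WT_H2AZ and 141 ± 17.2 CPM in H2AZ_4KR (SD, n = 3).

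LEU2, an enzyme gene of leucine synthesis that is deleted in BY4741, had 0 fragments in each WT_H2AZ library and 138 ± 18.3 CPM (SD, n = 3) in H2AZ_4KR. Set against the floor of 3 fragments per library, 0.172 CPM, it was at least 804-fold higher in H2AZ_4KR. Both groups of the Ino80 table also had LEU2 RNA, at 166 ± 14.9 CPM (SD, n = 3) in WT_Ino80 and 146 ± 21.6 CPM (SD, n = 3) in Ino80_K929R. MET17, another gene deleted in this background, had 0 fragments in all 12 libraries, and URA3 had at most 2 fragments in a library. HIS3 was detected in every library, at 164 ± 24.2 CPM (SD, n = 3) in WT_H2AZ, 139 ± 28.2 in H2AZ_4KR, 72.8 ± 13.4 in WT_Ino80 and 134 ± 7.09 in Ino80_K929R. LYS2 was at 159 ± 1.47, 142 ± 5.02, 141 ± 41.6 and 170 ± 25 CPM (SD, n = 3) in the same order. Neither HIS3 nor LYS2 passed the test in either mutant.

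**Figure D1:**
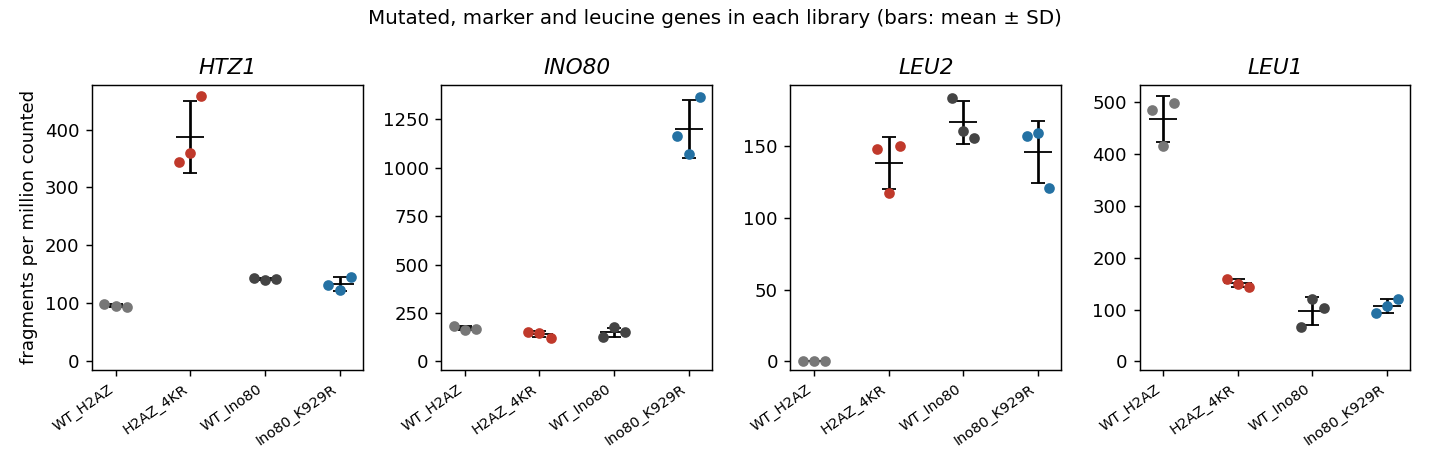
Levels of HTZ1, INO80, LEU2 and LEU1 in CPM in each of the 12 libraries by group, with points for libraries and bars for mean ± SD (n = 3). HTZ1 lay between 344 and 459 CPM in H2AZ_4KR, INO80 between 1073 and 1366 CPM in Ino80_K929R, and LEU2 had 0 fragments in WT_H2AZ.

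In H2AZ_4KR, 93 of 135 cytosolic ribosomal protein genes rose, while 17 of 21 glucose-repressed genes, 17 of 24 hexose transporter and glucose sensing genes and 17 of 59 stress genes fell. As lists, none of these passed with an estimated correlation between genes, with adjusted p = 0.155, 0.155, 0.15 and 0.456 in that order. RPS22A, a ribosomal protein gene, rose from 680 ± 62 to 1178 ± 43.6 CPM (SD, n = 3). SUC2, which encodes invertase and is repressed by glucose, fell from 1848 ± 234 to 414 ± 31.8 CPM (SD, n = 3). HXT4, a glucose transporter gene, fell from 4500 ± 639 to 1493 ± 203 CPM (SD, n = 3). ARN1, an iron uptake gene, rose from 95.6 ± 5.51 to 218 ± 28 CPM (SD, n = 3).

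Of 6106 genes tested, 739 changed, 292 of them up and 447 down. At an unadjusted p below 0.05 there were 2226 genes, against 305 by chance, and the groups did not overlap in 2712 genes (44.4%, against 10% by chance). DESeq2 called 767 genes, 723 of them shared. Scaling by total counts moved the median of all genes by -0.142 log2 units and gave 138 genes that rose and 671 that fell.

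HTZ1 rose by a log2 fold change of 2.15 (SE 0.127, adjusted p = 1.1e-05). DAN1, a cell wall mannoprotein gene, rose by 2.65 (SE 0.559, adjusted p = 0.0076), from 18.7 ± 8.9 to 106 ± 94.4 CPM (SD, n = 3), and by 1.63 without H2AZ_4KR replicate 3 (adjusted p = 0.0205). YPR137C-B, a Ty retrotransposon gene with many near-identical copies, rose by 1.72, the next highest value among genes that met the naming rule. HSP30, a plasma membrane stress protein gene, rose by 1.42 (adjusted p = 0.000235). FIT2, a cell wall mannoprotein gene of iron uptake, rose by 1.38 (adjusted p = 0.00174), from 455 ± 97.5 to 1078 ± 250 CPM (SD, n = 3). PDR12, an exporter gene for weak organic acids, rose by 1.37 (adjusted p = 0.000922), and TPO1, a polyamine exporter gene, by 1.20 (adjusted p = 0.000595). GPX2, a peroxidase gene, rose by 1.19 (adjusted p = 0.0151) but missed the threshold without WT_H2AZ replicate 3 (1.04, adjusted p = 0.0624) and stood at 0.74 without H2AZ_4KR replicate 2 (adjusted p = 0.0355).

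Among changed genes with a mean of at least 10 CPM and no overlap between the groups, PHO89, a phosphate transporter gene, had the steepest fall. It fell by -2.64 (SE 0.364, adjusted p = 0.00122), from 89.7 ± 45.7 to 12.9 ± 5.09 CPM (SD, n = 3). BOP2 fell by -2.26 (adjusted p = 4.35e-05) and SUC2 by -2.01 (SE 0.135, adjusted p = 2.28e-05). FAT3, of fatty acid uptake, and UBP11, a ubiquitin protease gene, each fell by -2.00. REG2, a regulator of glucose repression, fell by -1.98, the uncharacterised YMR206W by -1.97, the zinc finger gene YGR067C by -1.92 and PDH1, of propionate metabolism, by -1.86. NQM1, a transaldolase gene, fell with an adjusted p = 0.00494.

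**Figure D2:**
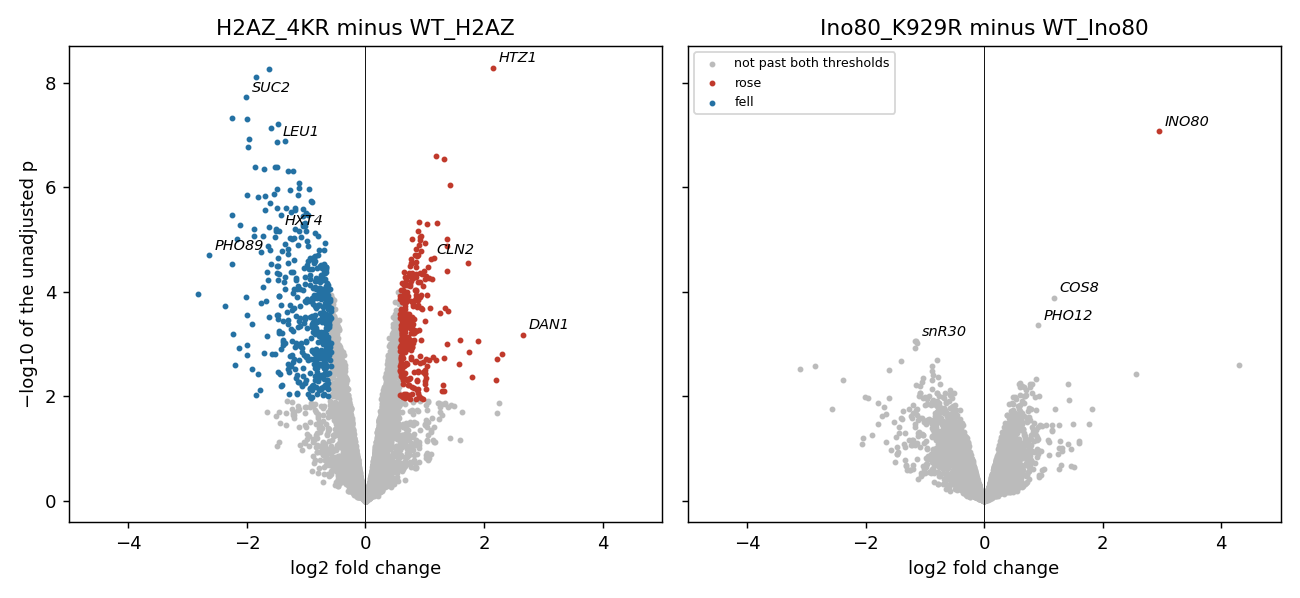
Log2 fold change (x axis) against unadjusted p on a log scale (y axis) for every gene tested in both mutant comparisons, with LEU2 left out. In H2AZ_4KR 292 genes rose, LEU2 among them though not drawn, and 447 fell, with HTZ1 at 2.15, and in the Ino80_K929R panel INO80 at 2.95 is the 1 gene past both thresholds.

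Of 135 cytosolic ribosomal protein genes, 93 rose, 0 fell and 42 did not pass, with 93 also when adjusted over the list alone. Their median log2 fold change was 0.64 and 134 were above 0, with RPS9A at 1.18, RPL12B at 0.91 and RPS19A at 0.92. The list passed at the preset correlation (adjusted p = 1.14e-45), with an adjusted p = 0.155 with an estimated correlation. Among 115 ribosome biogenesis genes, 11 rose, 0 fell and 104 did not pass, the same 11 and 0 adjusted over the list alone, with a median of 0.28 (adjusted p = 1.2e-06, and adjusted p = 0.588 with an estimated correlation). NSR1, a nucleolar protein gene, rose by 0.86, and NHP2, RRP9 and NOP10 by 0.59, 0.66 and 0.70. Under scaling by total counts these last genes fell short of the fold limit, at 0.45, 0.52 and 0.56, as NHP2 did at 0.57, 0.52 and 0.55 without WT_H2AZ replicate 1, WT_H2AZ replicate 2 or H2AZ_4KR replicate 1. After the gene length offset NHP2 and NOP10 stood at 0.51 and 0.54.

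Among 20 genes of purine and one-carbon synthesis, 4 rose and 16 did not pass, and 4 rose adjusted over the list alone (median 0.44, adjusted p = 2.37e-06, and adjusted p = 0.15 with an estimated correlation). IMD2 and IMD4, of guanine nucleotide synthesis, rose by 0.85 and 0.86, ADE57 by 0.67 and MTD1 by 0.81. MTD1 stood at 0.56 without H2AZ_4KR replicate 2, and ADE57 at 0.53 under total counts, both under the fold limit. Of 30 genes of the G1/S transition, 10 rose, 0 fell and 20 did not pass, with 10 adjusted over the list alone (median 0.32, adjusted p = 1e-05, and adjusted p = 0.278 with an estimated correlation). CLN2, a G1 cyclin gene, rose by 1.11, RNR1, of deoxynucleotide synthesis, by 1.12, the cohesin gene MCD1 by 0.94 and CDC21 by 0.79.

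The iron regulon had 8 genes that rose, 2 that fell and 17 that did not pass, with 8 and 2 adjusted over the list alone (median 0.35, adjusted p = 0.000497, and adjusted p = 0.278 with an estimated correlation). FTR1 and FET3, which form the high-affinity iron uptake complex, rose by 0.77 and 0.86 beside ARN1 (1.33) and FIT2. HMX1, the heme oxygenase gene, and FRE4 fell by -1.01 and -0.78. Of 26 Hsf1-dependent chaperone genes, 3 rose and 23 did not pass, and 3 rose adjusted over the list alone (median 0.24, adjusted p = 0.00646, and adjusted p = 0.581 with an estimated correlation). KAR2 and SSA2 each rose by 0.82. The chaperone list missed the threshold without H2AZ_4KR replicate 2 (median 0.16, adjusted p = 0.0809).

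The core histone list held 9 genes, among them HHO1, which encodes a linker histone. Of these 9 genes 1 rose, HTA2 by 0.61, and 8 did not pass, with 1 adjusted over the list alone (median 0.24, adjusted p = 0.0482, and adjusted p = 0.561 with an estimated correlation). The histone list passed neither under total counts (adjusted p = 0.0594) nor without WT_H2AZ replicate 1 (0.155), H2AZ_4KR replicate 2 (0.134) or H2AZ_4KR replicate 3 (0.0706), nor after the gene length offset (0.206). HTA2 stood at 0.47 under total counts, 0.51 after the length offset, 0.58 without WT_H2AZ replicate 2 and 0.53 without H2AZ_4KR replicate 2, under the fold limit. Of 11 housekeeping reference genes 1 rose, IPP1 by 0.61, and 10 did not pass, with 1 adjusted over the list alone (median 0.29, adjusted p = 0.0196, and adjusted p = 0.278 with an estimated correlation). IPP1 stood at 0.47 under total counts, 0.57 without WT_H2AZ replicate 2 and 0.56 without H2AZ_4KR replicate 1.

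Of 21 glucose-repressed genes of gluconeogenesis and the glyoxylate cycle, 17 fell, 0 rose and 4 did not pass, with 17 adjusted over the list alone. Their median was -0.94 (adjusted p = 8.13e-15, and adjusted p = 0.155 with an estimated correlation). YAT2, a carnitine acetyltransferase gene, fell by -1.84, the lactate transporter gene JEN1 by -1.73 and CAT8, an activator of gluconeogenic genes, by -1.30. Of 24 hexose transporter and glucose sensing genes, 17 fell and 7 did not pass, with 18 adjusted over the list alone (median -0.85, adjusted p = 1.21e-12, and adjusted p = 0.15 with an estimated correlation). HXT13 fell by -1.49, HXT4 by -1.45, HXT5 by -1.06 and the sensor gene SNF3 by -0.86. Among 59 genes induced in the environmental stress response, 17 fell, 1 rose (HSP30) and 41 did not pass, with 18 and 1 adjusted over the list alone. The stress list had a median of -0.46 (adjusted p = 2.52e-09, and adjusted p = 0.456 with an estimated correlation), with DDR2 down by -1.20, RTN2 by -1.02 and GAC1 by -0.79.

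Of 10 galactose genes, 6 fell and 4 did not pass, and 6 fell adjusted over the list alone (median -0.67, adjusted p = 2.9e-05, and adjusted p = 0.15 with an estimated correlation). GAL3 fell by -1.69, GAL7 by -1.63, MTH1 by -0.84 and GAL4 by -0.63, the last under the fold limit without WT_H2AZ replicate 2 (-0.58) or H2AZ_4KR replicate 1 (-0.54) and after the length offset (-0.58). Of 26 genes of fatty acid oxidation and the peroxisome, 6 fell and 20 did not pass, and 6 fell adjusted over the list alone (median -0.22, adjusted p = 0.00399, and adjusted p = 0.278 with an estimated correlation). POX1, of the initial oxidation step, fell by -1.24, FAA2 by -1 and the transporter genes PXA1 and PXA2 by -1.01 and -0.65, with PXA2 at -0.57 without H2AZ_4KR replicate 1. Under nitrogen catabolite repression, 8 of 27 genes fell, 1 rose and 18 did not pass, with 8 and 1 adjusted over the list alone. That list had a median of -0.26 (adjusted p = 0.0074, and adjusted p = 0.456 with an estimated correlation), and of -0.45 without H2AZ_4KR replicate 3. GDH2 fell by -0.90, DAL2 by -1.45 and PUT1 by -1.11, while DUR12, the urea amidolyase gene, rose by 0.80.

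Of 21 genes of thiamine and vitamin B6 synthesis, 6 fell and 15 did not pass, and 9 fell adjusted over the list alone (median -0.37, adjusted p = 0.0107, and adjusted p = 0.278 with an estimated correlation). SNZ2 fell by -1.66 and SNZ3 by -1.47, both members of near-identical families. Of 16 NAD synthesis genes, 2 fell, NRT1 by -0.95 and BNA5 by -1.26, and 14 did not pass, with 2 adjusted over the list alone (median -0.18, adjusted p = 0.0107, and adjusted p = 0.278 with an estimated correlation). The phosphate regulon had 4 genes that fell and 17 that did not pass, with 4 adjusted over the list alone (median -0.18, adjusted p = 0.0482, and adjusted p = 0.278 with an estimated correlation). Beside PHO89, the acid phosphatase gene PHO11 fell by -0.96 and PHM8 by -0.64, the latter at -0.57 without WT_H2AZ replicate 1 and -0.47 without H2AZ_4KR replicate 2. The phosphate list missed the threshold under total counts (adjusted p = 0.0511), after the length offset (0.0678) and without WT_H2AZ replicate 1 (0.054), WT_H2AZ replicate 2 (0.0538), H2AZ_4KR replicate 1 (0.0797) or H2AZ_4KR replicate 2 (0.104).

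Of 24 pheromone response genes, 5 fell, 1 rose and 18 did not pass, with 5 and 1 adjusted over the list alone (median -0.34, adjusted p = 0.0109, and adjusted p = 0.456 with an estimated correlation). FUS1, a cell fusion gene, fell by -1.52, PRM10 by -1.21, FIG2 by -0.74 and AGA1 by -0.83, and FIG1 rose by 1.04. AGA1 had an adjusted p = 0.0617 without H2AZ_4KR replicate 3. Of 12 genes of filamentous growth and flocculation, 4 fell, 1 rose and 7 did not pass, with 4 and 1 adjusted over the list alone (median -0.48, adjusted p = 0.0468, and adjusted p = 0.418 with an estimated correlation). TEC1, a transcription factor gene of filamentation, fell by -0.94, FLO5 by -0.74 and FLO11 by -0.66, and the cyclin gene CLN1 rose by 0.75. Without WT_H2AZ replicate 1, FLO5 and FLO11 stood at -0.58 and -0.56, and CLN1 stood at 0.54 without H2AZ_4KR replicate 1. The filamentous growth list missed the threshold under total counts (adjusted p = 0.0518), after the length offset (0.0549) and without WT_H2AZ replicate 1 (0.0883), H2AZ_4KR replicate 2 (0.0687) or H2AZ_4KR replicate 3 (0.124).

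Within 20 kb of a chromosome end, 62 of 210 genes fell (29.5%), against 385 of 5896 other genes (6.53%), an odds ratio of 5.99 (Fisher's exact test, two-sided, p = 5.26e-23). Rises were found in 5 of the 210 genes (2.38%) and 287 of the others (4.87%, Fisher's exact test, p = 0.101). Genes are not independent replicates, so the p-values of Fisher's exact test here do not measure the spread between samples. The list had a median of -0.36 (adjusted p = 3.92e-08, and adjusted p = 0.155 with an estimated correlation), with 72 genes that fell and 5 that rose adjusted over the list alone. COS10 fell by -1.71, EMA35 by -1.62 and YDR541C by -1.54. A further filter left out multigene families, whose near-identical copies share reads, and also every gene without a gene name. Of the genes kept, 39 of 100 near ends fell (39%), against 305 of 5019 (6.08%), an odds ratio of 9.87 (Fisher's exact test, p = 5.1e-21). Because unnamed genes were dropped too, this filter does not isolate the part of shared reads.

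In all, 20 of 43 lists passed at the preset correlation, 8 up and 12 down, and 0 with an estimated correlation (lowest adjusted p = 0.15), while fry called 21. Of these 20, directional fry did not call core histones (adjusted p = 0.0803), ribosome biogenesis (adjusted p = 0.126) or the Hsf1 chaperones (adjusted p = 0.098). The estimated correlation was 0.263 for ribosomal protein and 0.386 for stress genes. It was 0.0016 for purine and one-carbon synthesis and -0.087 for galactose genes, below the preset 0.01, yet each had an adjusted p = 0.15. For these last lists the lost call cannot be laid to members that move together. Under total counts the medians were 0.14 for ribosome biogenesis, 0.10 for chaperones, 0.21 for iron, 0.17 for G1/S, 0.14 for housekeeping and 0.10 for histone genes, and -0.36 for fatty acid oxidation, -0.41 for nitrogen catabolite repression, -0.33 for NAD synthesis and -0.32 for phosphate genes. Among the lists that did not pass, that of the SWR1 complex, which places H2A.Z in chromatin, had SWR1 (0.59) and HTZ1 up, ARP6 (-0.60) down and 13 genes not past. Of 21 glycolysis and fermentation genes, 3 rose, TPI1 by 0.62, PGK1 by 0.64 and ENO2 by 0.79, and 4 fell, among them HXK2 by -0.67 and PFK26 by -0.92. Of 59 amino acid synthesis genes under Gcn4, 7 fell and 2 rose, with LEU1, which acts in leucine synthesis, at -1.49 and GLN1, glutamine synthetase, at 0.81. The 12 genes with a COS name, all but COS111 of the subtelomeric COS family, had a median of 0.06 although the test pointed down. COS10, COS111 (-1.50) and COS12 (-0.75) were among 3 that fell. Of 7 a-specific and 5 alpha-specific genes, markers of the mating types, 0 rose and 0 fell by edgeR. The names in these lists that did not pass were chosen after their values were seen.

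**Figure D3:**
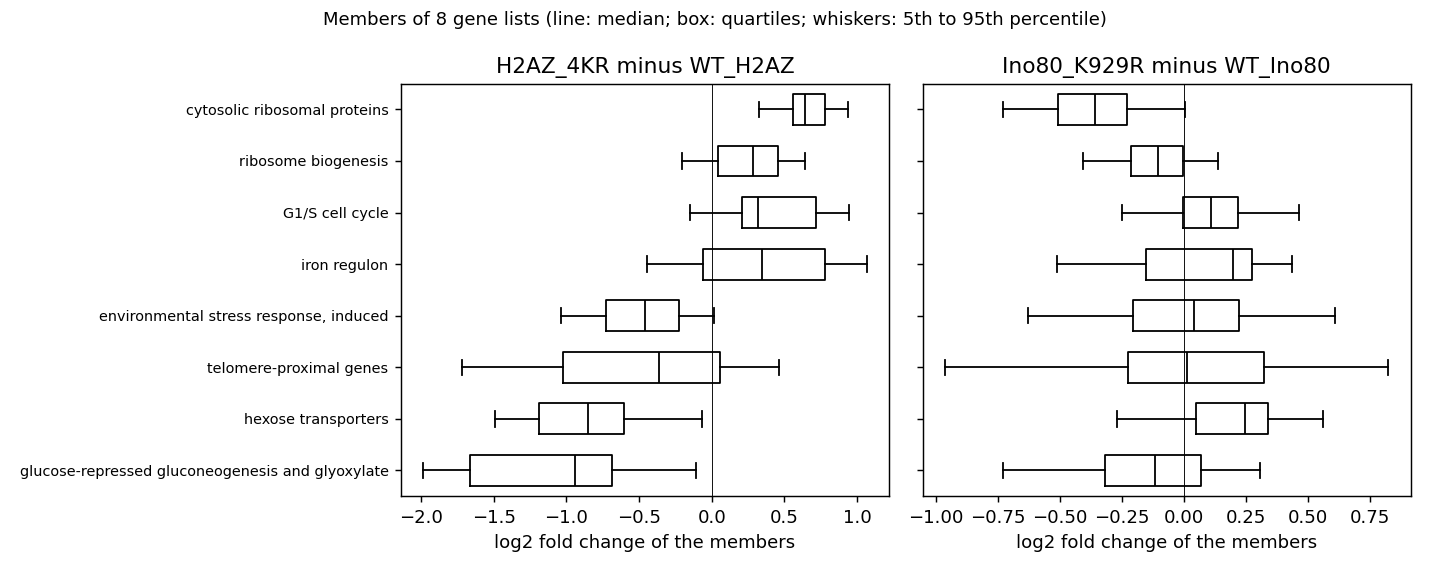
Log2 fold changes of the members of 8 gene lists in H2AZ_4KR and in Ino80_K929R, as boxes from the lower to the upper quartile with the median and whiskers from the 5th to the 95th percentile. Cytosolic ribosomal protein genes had a median of 0.64 in H2AZ_4KR and -0.36 in Ino80_K929R, and hexose transporter genes one of -0.85 in H2AZ_4KR.

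In Ino80_K929R, INO80 itself rose by a log2 fold change of 2.95 (SE 0.158, adjusted p = 0.000521), and it was the 1 gene of 6161 to pass. COS8, a subtelomeric gene, stood at 102 ± 10.1 CPM (SD, n = 3) in the mutant and 43.8 ± 9.1 in WT_Ino80, and PHO12, an acid phosphatase gene, at 123 ± 23 and 62.9 ± 2.56. The small nucleolar RNA snR30, needed for processing of ribosomal RNA, stood at 164 ± 20.6 CPM (SD, n = 3) in the mutant and 348 ± 51.1 in WT_Ino80. BUD23, an rRNA methyltransferase gene, stood at 30.1 ± 6.26 and 64.2 ± 11.8 CPM (SD, n = 3).

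By edgeR, 380 genes had an unadjusted p below 0.05, against 308 by chance, and the groups did not overlap in 914 genes (14.8%, against 10% by chance). DESeq2 called 8 genes. INO80, COS8 (log2 fold change 1.19, adjusted p = 9.64e-06) and PHO12 (0.92, adjusted p = 0.00285) were higher by DESeq2. Lower by DESeq2 were snR30 (-1.14, adjusted p = 0.00979), snR37 (-1.16, adjusted p = 0.00979), snR83 (-1.13, adjusted p = 0.0106), BUD23 (-1.16, adjusted p = 0.0162) and snR128 (-1.39, adjusted p = 0.0233). In edgeR the adjusted p was 0.398 for COS8 and 0.722 for PHO12. The fit of all 12 libraries called INO80 (adjusted p = 2.31e-07) and COS8 (adjusted p = 0.00282).

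WT_Ino80 replicate 1 and Ino80_K929R replicate 3 stood apart from their own groups. On the leading principal component (51.7% of the variance) the WT_Ino80 libraries lay at 44.6, -14 and -0.495 and the mutants at 1.82, -4.18 and -27.7. Chi-square per degree of freedom between libraries was 257 and 174 for WT_Ino80 replicate 1 against its group, with 84 between the others, and 206 and 141 for Ino80_K929R replicate 3, with 34.5 between the others. The median of the stress response genes was 6.02 log2 CPM in Ino80_K929R replicate 3, against 7.84 and 7.77 in the other mutant libraries. In WT_Ino80 replicates 1, 2 and 3 that median was 8.095, 6.747 and 7.583, so replicate 2 was low among the wild types. Levels in WT_Ino80 replicate 1 declined with gene length against the mean of the table (Spearman's rho across genes -0.597), while the other libraries had rho from 0.0958 to 0.374. Log2 fold changes in Ino80_K929R rose with coding or exon length (rho across genes 0.546), from a median of -0.36 in 382 genes of at most 300 bp to 0.19 in genes over 2000 bp. The same rho was -0.131 in H2AZ_4KR, and genes are not independent replicates.

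**Figure D4:**
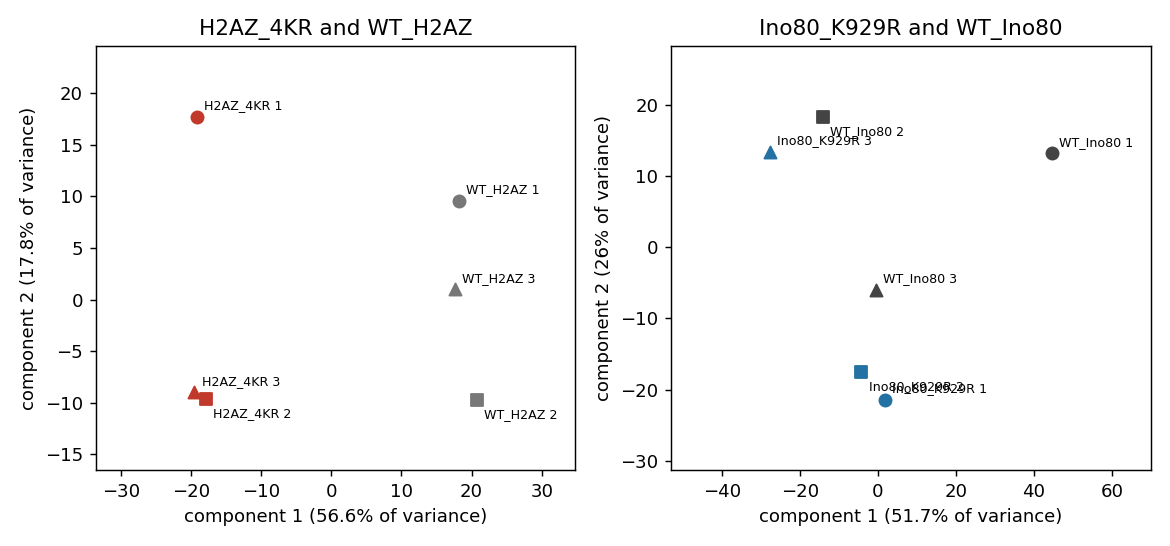
Principal components 1 and 2 of log2 CPM in each table, 1 point per library, coloured by group. Component 1 separates H2AZ_4KR from WT_H2AZ (56.6% of the variance), and in the Ino80 table (51.7%) WT_Ino80 replicate 1 lies at 44.6 and Ino80_K929R replicate 3 at -27.7, each apart from its group.

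**Figure D5:**
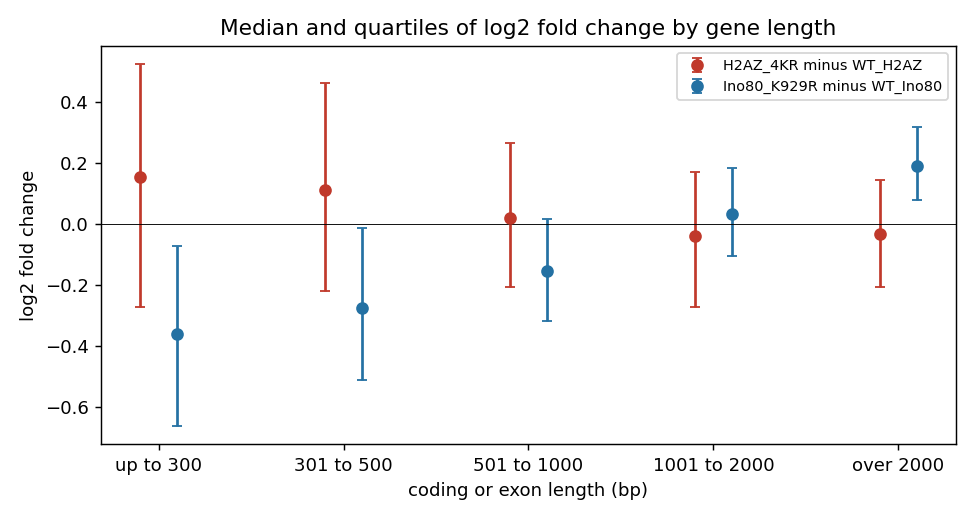
Median log2 fold change with quartiles (y axis) by bin of coding or exon length (x axis) in both mutant comparisons. In Ino80_K929R the medians run from -0.36 in genes of at most 300 bp to 0.19 in genes over 2000 bp, and in H2AZ_4KR from 0.155 to -0.0315.

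Of 43 lists in Ino80_K929R, 11 passed at the preset correlation, 6 up and 5 down, 0 with an estimated correlation (lowest adjusted p = 0.58) and 0 by directional fry. No member of these 11 lists passed by edgeR over all genes, while DESeq2 called COS8 and PHO12. Adjusted over the list alone, COS8 and PHO12 passed in their lists and 0 members in the other 9 lists. The 135 cytosolic ribosomal protein genes had a median of -0.36 (adjusted p = 3.54e-14, and adjusted p = 0.871 with an estimated correlation), with RPL35A and RPL38 each at -0.63. Without WT_Ino80 replicate 1 that median was -0.09, with RPL35A at -0.33, RPL38 at -0.32 and RPL41A at -0.43 in place of -1.09, and after the length offset the median was -0.15. The 28 cell wall integrity genes had a median of 0.37 (adjusted p = 1.62e-07, and adjusted p = 0.599 with an estimated correlation), with PST1 at 0.58, the transcription factor gene RLM1 at 0.81 and CRH1, a chitin transglycosylase gene, at 0.54. After the length offset that median was 0.25 (adjusted p = 5.01e-08 at the preset correlation). The 12 COS genes had a median of 0.60 (adjusted p = 3.1e-06, and adjusted p = 0.599 with an estimated correlation), with COS7 at 0.83.

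Genes for mitochondrial ribosomal proteins (72 genes, median -0.17, adjusted p = 0.000764) and the core histone list with HHO1 (9 genes, median -0.33, adjusted p = 0.0137) each had an adjusted p = 0.871 with an estimated correlation. Without WT_Ino80 replicate 1 neither list passed, with medians of -0.03 (adjusted p = 0.413) and -0.07 (adjusted p = 0.164), nor did either after the length offset (adjusted p = 0.672 for each). The mitochondrial median was -0.27 without WT_Ino80 replicate 3 and -0.10 under total counts, and the histone median was -0.51 without WT_Ino80 replicate 2. HHT1 and HHF1, for histones H3 and H4, were at -0.63 and -0.58, at -0.35 and -0.32 without WT_Ino80 replicate 1, and at -0.36 and -0.28 after the length offset. The 21 phosphate regulon genes had a median of 0.16 (adjusted p = 0.00782, and adjusted p = 0.584 with an estimated correlation), and the list missed the threshold without WT_Ino80 replicate 3 (adjusted p = 0.11). PHO89 stood at 1.82, or 0.97 without Ino80_K929R replicate 1, without passing. Thiamine and vitamin B6 genes had a median of -0.25 (adjusted p = 0.00245, and adjusted p = 0.584 with an estimated correlation) and missed the threshold without WT_Ino80 replicate 2 (adjusted p = 0.0506), with THI4 at -0.80.

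The ribosome biogenesis list had a median of -0.10 (adjusted p = 0.0218, and adjusted p = 0.871 with an estimated correlation). This became -0.16 without WT_Ino80 replicate 1, 0.04 without WT_Ino80 replicate 2, 0.0035 without Ino80_K929R replicate 1, 0.0098 without Ino80_K929R replicate 2 and -0.31 without Ino80_K929R replicate 3. It was -0.18 after the length offset, and the call was also lost under total counts (adjusted p = 0.0718). Genes of G2/M (median 0.18, adjusted p = 0.0089), of M/G1 in daughter cells (0.17, adjusted p = 0.0218) and of the TCA cycle (0.10, adjusted p = 0.0313) each had an adjusted p = 0.871 with an estimated correlation. After the length offset none of these passed, with adjusted p = 0.182, 0.224 and 0.0917. The G2/M list was lost without WT_Ino80 replicate 3 (adjusted p = 0.11) or Ino80_K929R replicate 3 (0.235), and the M/G1 list without WT_Ino80 replicate 1 (0.228), WT_Ino80 replicate 3 (0.11) or Ino80_K929R replicate 3 (0.243). The TCA list was lost without WT_Ino80 replicate 2 (0.219), WT_Ino80 replicate 3 (0.0757), Ino80_K929R replicate 1 (0.337) or Ino80_K929R replicate 2 (0.0694). Where these calls held, the G2/M median was 0.10 and 0.33 without WT_Ino80 replicates 1 and 2, the M/G1 median was 0.37 without WT_Ino80 replicate 2, and the TCA median was 0.20 without WT_Ino80 replicate 1 and 0.26 without Ino80_K929R replicate 3. In the list of the INO80 complex, INO80 rose and 13 genes did not pass, with a median of -0.11 while the test pointed up (adjusted p = 0.216). The 221 telomere-proximal genes had a median of 0.01, and 0 passed by edgeR, with 2 past when adjusted over the list alone.

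In a list chosen after seeing the data, 72 snoRNA and snRNA genes had a median of -0.70 in Ino80_K929R (adjusted p = 3.37e-23, and adjusted p = 0.417 with an estimated correlation). By edgeR 0 passed over all genes and 8 fell adjusted over the list alone, and DESeq2 called 4 of them. Without WT_Ino80 replicate 1 the median was -0.53, and after the length offset it was -0.32. Median levels were 2.54, 2.34 and 2.29 log2 CPM in the WT_Ino80 libraries and 1.78, 1.72 and 1.55 in the mutant libraries. In H2AZ_4KR, 8 of 67 such genes rose, 1 fell and 58 did not pass, with 5 and 1 adjusted over the list alone (median 0.31, adjusted p = 0.00686, and adjusted p = 0.444 with an estimated correlation). Of 11 tRNA genes in H2AZ_4KR, 1 rose and 1 fell, with a median of 0.42 but a mean of -0.06 (adjusted p = 0.904), and 12 tRNA genes in Ino80_K929R had a median of -0.09 (adjusted p = 0.224).

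The change from its own wild type differed between the mutants in 265 of 6235 genes in the test of the difference itself. Of these, 124 were more positive and 141 more negative in H2AZ_4KR. With a replicate block, 32 genes differed. A strain or marker difference, such as the LEU2 RNA not detected in WT_H2AZ, cannot be told apart from the mutations in this contrast. HTZ1 (difference of log2 fold changes 2.30, adjusted p = 7.48e-05) and INO80 (-3.10, adjusted p = 2.35e-06) differed as the mutated genes, and LEU2 with an adjusted p = 2.68e-07. The uncharacterised YFR035C (2.05, adjusted p = 0.0274), snR30 (2.02, adjusted p = 0.0101) and snR83 (1.88, adjusted p = 0.028) were more positive in H2AZ_4KR. PHO89 (-4.46, adjusted p = 0.0193), BOP2 (-3.03, adjusted p = 0.0193), FAT3 (-2.55, adjusted p = 0.0192) and PDH1 (-2.55, adjusted p = 0.0123) were more negative. The count was 723 by DESeq2, and under total counts, which moved the median by -0.185 log2 units, 110 differences were positive and 274 negative. It was 32, 33 and 44 without WT_H2AZ replicates 1, 2 and 3, and 122, 26 and 31 without those of H2AZ_4KR. It was 420 and 430 without WT_Ino80 replicates 2 and 3, and 42, 37 and 594 without Ino80_K929R replicates 1, 2 and 3.

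Across 6069 genes tested in both mutants, log2 fold changes had a Pearson's r of -0.176 and a Spearman's rho of -0.216, with 42.1% of genes of the same sign. The correlation is across genes, which are not independent replicates, and no p is given. Pearson's r was -0.0895 without WT_Ino80 replicate 2, -0.0516 without Ino80_K929R replicate 1 and -0.296 without Ino80_K929R replicate 3. Among 738 genes changed in H2AZ_4KR, 35.9% had the same sign in Ino80_K929R (r -0.308). No gene changed in both mutants by edgeR, where 0.0481 shared rises would occur by chance, as INO80 was the 1 changed gene in Ino80_K929R.

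Between the wild types, SUC2 stood at 284 ± 77.8 CPM (SD, n = 3) in WT_Ino80 and 1848 ± 234 in WT_H2AZ, and PHO89 at 12 ± 4.37 and 89.7 ± 45.7. AGA1, an agglutinin gene, stood at 33.6 ± 20.2 and 291 ± 94.5 CPM (SD, n = 3). Higher in WT_Ino80 were snR30, at 348 ± 51.1 against 30.01 ± 4.31 CPM (SD, n = 3), and ADH2, an alcohol dehydrogenase gene repressed by glucose, at 234 ± 73.8 against 35.1 ± 4.08. In all, 2036 genes differed, 1101 of them higher and 935 lower in WT_Ino80. Strain construction and batch cannot be told apart in this contrast, since each wild type is in a table of its own.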

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

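The tests of strain and mutation as sources of the ribosomal protein and snoRNA patterns, the tests that left out WT_Ino80 replicate 1, the snoRNA list itself and the split counts for genes changed in each mutant were chosen after their results were seen.

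The change from its own wild type differed between the mutants, in the test of the difference itself, for 14 of the genes named. For gene lists this held for 19 of 43 at the preset correlation and for 0 with an estimated correlation. Strain and mutation cannot be told apart in this contrast. Among genes, the difference of log2 fold changes (H2AZ_4KR less Ino80_K929R) was 2.30 for HTZ1, 1.59 for the iron uptake gene FIT2 (adjusted p = 0.0394) and 0.98 for ARN1 (adjusted p = 0.0464). It was 2.05 for YFR035C, 2.02 for snR30 and 1.88 for snR83. LEU2 differed with an adjusted p = 2.68e-07. It was -4.46 for PHO89, -3.03 for BOP2, -2.31 for SUC2 (adjusted p = 0.0193), -2.55 for FAT3, -2.09 for UBP11 (adjusted p = 0.0121), -2.547 for PDH1 and -3.10 for INO80.

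Among lists, the median difference was 1.03 for cytosolic ribosomal proteins (adjusted p = 1.18e-44), 0.33 for ribosome biogenesis (4.25e-06), 0.49 for purine and one-carbon synthesis (0.00109), 0.48 for core histones (0.00309), 0.48 for housekeeping reference genes (0.0254) and 0.23 for mitochondrial ribosomal proteins (0.003). It was -1.05 for hexose transporters (4.88e-06), -0.87 for glucose-repressed genes (8.98e-05), -0.78 for galactose genes (0.00227) and -0.49 for the environmental stress response (0.0254). It was also -0.44 for telomere-proximal genes (4.25e-06) and -0.65 for genes with a COS name (0.00168). It was -0.69 for filamentous growth (0.00984), -0.60 for the phosphate regulon (0.00213), -0.53 for nitrogen catabolite repression (0.00136), -0.38 for the TCA cycle (0.022), -0.32 for fatty acid oxidation (0.013), -0.28 for cell wall integrity (0.0254) and -0.19 for NAD synthesis (0.0298). These values are camera adjusted p-values at the preset correlation, and 0 of the 43 lists passed with an estimated correlation (lowest adjusted p = 0.21).

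In H2AZ_4KR, 93 of 135 ribosomal protein genes rose and 17 of 21 glucose-repressed, 17 of 24 hexose transporter and 17 of 59 stress genes fell, although as lists none passed with an estimated correlation (adjusted p = 0.155, 0.155, 0.15 and 0.456). The values argue against a gene length trend as the whole cause, since the ribosomal protein median was 0.59 after the length offset (0.64 before). Under the other scalings that median was 0.51 at its lowest. RLE factors and total counts moved the median of all genes by 0.0119 and -0.142 log2 units, too little to bring 0.64 to 0. They therefore cannot exclude a larger error of scaling, although a shift of all genes alike could not give both the rise and the falls. WT_Ino80 less WT_H2AZ gave a ribosomal protein median of 0.86 and H2AZ_4KR less WT_Ino80 one of -0.18. In these contrasts the medians were -0.28 and -0.64 for glucose-repressed genes and -0.35 and -0.52 for hexose transporter genes. For stress genes they were -0.86 and 0.49, the second against the direction of the pattern. Without WT_Ino80 replicate 1, left out after its values were seen, the ribosomal protein medians were 0.58 and 0.13, so the sign of the second rests on that library. The glucose-repressed medians were then -0.51 and -0.56, those of hexose transporter genes -0.27 and -0.59, and those of stress genes -1.28 and 0.74. For this pattern, the H2AZ_4KR mutation cannot be told apart from a strain or marker difference, such as the LEU2 RNA not detected in WT_H2AZ. Nor can either be told apart from the higher HTZ1 RNA, because all of them part the same libraries.

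In Ino80_K929R, ribosomal protein genes had a median of -0.36, with 0 of 135 past by edgeR or DESeq2. Of all 6161 genes tested, 1 passed by edgeR, and DESeq2 called 8. As a list the ribosomal protein genes had an adjusted p = 0.871 with an estimated correlation and 0.692 by fry. Without WT_Ino80 replicate 1 the median was -0.0903 (adjusted p = 0.0033), so most of the shift may come from that library. The length offset left -0.15 (adjusted p = 0.00636). The trend with length cannot be told apart from the pattern, because ribosomal protein genes are short. How much of the trend comes from WT_Ino80 replicate 1 was not measured. Its rho with length was -0.597, against 0.0958 and 0.126 in WT_Ino80 replicates 2 and 3 and 0.193, 0.264 and 0.374 in the mutant libraries. The mutation also stays open: the lowest wild-type library median lay 0.0454 log2 units above the highest mutant library median, a gap smaller than the spread between libraries.

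The snoRNA and snRNA genes had a median of -0.70 in Ino80_K929R, with 0 of 72 past by edgeR and 4 by DESeq2, and as a list had an adjusted p = 0.417 with an estimated correlation and 0.221 by fry. The tables argue against WT_Ino80 replicate 1 as the whole source, since the median without it was -0.53. The length offset left -0.32 (adjusted p = 1.44e-07), a test that keeps the length trend open, because these genes are among the short ones that set the trend. At up to 300 bp the median was -0.641 for 63 snoRNA and snRNA genes (median length 124 bp) and -0.318 for 260 coding genes (median length 219 bp). The mutation cannot be told apart from a difference in recovery of short RNA between the groups, although the lowest wild-type library median lay 0.51 log2 units above the highest mutant library median.

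Among the 10 splits of 6 libraries into 3 and 3, only the real split, 1 of 10, gave as many changed genes in H2AZ_4KR (739, highest other 0), in Ino80_K929R (1, highest other 0) and between the wild types (2036, highest other 0). For gene lists, 2 of 10 splits of the H2AZ table gave as many lists as the real 20 (highest other 23), and 7 of 10 splits of the Ino80 table gave as many as the real 11 (highest other 16). These splits are too few for a share under 0.05. For the difference between the mutant effects, 3 of 100 splits gave as many genes as the real 265, with the highest other at 681. That split kept the H2AZ table as it is and set WT_Ino80 replicates 1 and 2 with Ino80_K929R replicate 3, which points to a structure among the Ino80 samples other than the genotype. Most of the other splits also broke up the groups of the H2AZ table, so the share of 3 in 100 does not exclude chance for the grouping of the Ino80 libraries.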

How the results depend on the processing

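The gene length offset, the matching of list names without synonyms and the relation of both effects with single libraries left out were chosen after the results were seen. The 739 genes changed in H2AZ_4KR became 346 in 1 fit of all 12 libraries (341 of them shared), where groups share 1 estimate of the spread, 113 by glmTreat at 1.5-fold, 1400 without a fold limit and 239 at a fold over 2. Other tools, scalings and left-out libraries gave 617 to 809 genes, with 0 sign changes among shared calls. The 1 gene of Ino80_K929R became 8 by DESeq2 and 2 in the fit of all 12 libraries. The 265 genes that differed between the mutant effects became 723 by DESeq2, 32 with a replicate block, and 26 to 594 with 1 library left out. The 2036 genes that differed between the wild types became 941 at a fold over 2. Of the 20 lists past the threshold in H2AZ_4KR, 0 passed with an estimated correlation, and mixed fry called 39 lists, these 20 among them. In Ino80_K929R, where 11 lists passed, 0 passed with an estimated correlation and 0 by directional fry. There mixed fry called 1 list, the INO80 complex, which is not among the 11, and 7 lists passed after the length offset, 6 of them among the 11. With a replicate block, adjusted p was 0.0519 for both the core histone and the phosphate list in H2AZ_4KR. The odds ratio near telomeres was above 1 under every distance, gene filter, tool, scaling and left-out library run. It ran from 4.19 within 50 kb to 14.4 within 10 kb without multigene families and genes without a gene name. Pearson's r between the effects ranged from -0.296 to -0.0516 with 1 library left out. Log2 fold changes near 0 turned sign. In H2AZ_4KR with 1 library left out, HIS3 ranged from -0.2754 to 0.007809 (0.007374 without WT_H2AZ replicate 3) and LYS2 from -0.05874 to 0.01843 (0.01136 without H2AZ_4KR replicate 2). In Ino80_K929R LYS2 was -0.03698 after the length offset. Apart from the fits named with their construction, the cause was not tested. Whether replicate numbers pair the samples stays undecided with 3 samples per group. Each sample's best correlation was with its own number for 2 of 3 mutant and 2 of 3 wild-type samples in the H2AZ table. In the Ino80 table this held for 1 of 3 and 1 of 3. A replicate block gave 776 changed genes in H2AZ_4KR. At this spread the Ino80 table recovered 14 of 50 simulated 2-fold changes at an adjusted p below 0.05 without the fold limit. Changes of that size were therefore mostly not detectable there.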

Other observations

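Gene list tests between the wild types, between H2AZ_4KR and WT_Ino80, and of the Leu3 target genes were chosen after the results were seen.

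WT_Ino80 had more RNA of ribosome biogenesis genes than WT_H2AZ, with 103 of 115 higher, 0 lower and a median log2 difference of 1.02 (adjusted p = 2.77e-30, and adjusted p = 0.3135 with an estimated correlation). NSR1, a nucleolar protein gene, stood at 517 ± 74.7 CPM (SD, n = 3) in WT_Ino80 and 150 ± 10.2 CPM in WT_H2AZ. Of 135 cytosolic ribosomal protein genes, 102 were higher and 0 lower (median 0.86, adjusted p = 1.65e-16, and adjusted p = 0.5246 with an estimated correlation). Of 21 thiamine and vitamin B6 genes, 10 were higher and 0 lower (median 0.71, adjusted p = 0.00116, and adjusted p = 0.3019 with an estimated correlation).

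Lower in WT_Ino80 were 9 of 12 genes of filamentous growth and flocculation, with 1 higher (median -0.80, adjusted p = 0.004351, and adjusted p = 0.3135 with an estimated correlation), and 8 of 12 COS genes (median -0.82, adjusted p = 0.00116, and adjusted p = 0.3135 with an estimated correlation). FLO11, a cell surface flocculin gene, stood at 11.8 ± 6.16 CPM (SD, n = 3) in WT_Ino80 and 30 ± 3.72 CPM in WT_H2AZ. Of 7 a-specific genes, 5 were lower (median -0.85, adjusted p = 0.00302, and adjusted p = 0.3135 with an estimated correlation), with MFA2, a mating pheromone gene, at 58.7 ± 14.1 and 267 ± 119 CPM (SD, n = 3). Of 6 genes of the alpha-specific and silent mating locus list, 3 were higher in WT_Ino80 and 1 lower (median 0.54, adjusted p = 0.296, and adjusted p = 0.5246 with an estimated correlation), and its median log2 CPM was 3.85, 3.62 and 3.84 in the WT_Ino80 libraries and 2.02, 1.74 and 2.05 in those of WT_H2AZ. STE3, a pheromone receptor gene, stood at 14.1 ± 1.06 and 2.49 ± 0.267 CPM (SD, n = 3), while SAG1, an agglutinin gene, was the 1 lower. Of 34 meiosis genes, 13 were higher and 3 lower (median 0.61, adjusted p = 0.0579, and adjusted p = 0.5246 with an estimated correlation). Of 19 TCA cycle genes, 10 were lower and 0 higher (median -0.64, adjusted p = 0.00116, and adjusted p = 0.5246 with an estimated correlation), with CIT2, citrate synthase of the peroxisome, at 81.2 ± 26.8 and 268 ± 17.7 CPM (SD, n = 3). HSP12, a stress gene, was higher in WT_Ino80, at 1066 ± 597 against 218 ± 126 CPM (SD, n = 3), although 23 of 59 genes of the environmental stress response were lower and 5 higher (median -0.86, adjusted p = 0.000725, and adjusted p = 0.6748 with an estimated correlation).

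Against WT_Ino80 in place of its own wild type, H2AZ_4KR had lower RNA of 79 of 115 ribosome biogenesis genes, 0 higher (median -0.87, adjusted p = 3.48e-20, and adjusted p = 0.4332 with an estimated correlation). Of 21 glucose-repressed genes, 11 were lower (median -0.64, adjusted p = 0.00166, and adjusted p = 0.5589 with an estimated correlation). Lower too were 11 of 21 thiamine and vitamin B6 genes, with 0 higher (median -1.03, adjusted p = 2.06e-08). That list also passed with an estimated correlation (adjusted p = 0.0128). Telomere-proximal genes were lower in 78 of 227 cases and higher in 15 (median -0.47, adjusted p = 5.1e-06, and adjusted p = 0.275 with an estimated correlation). Of 26 chaperone genes, 14 were higher (median 0.65, adjusted p = 1.69e-06, and adjusted p = 0.4154 with an estimated correlation). These libraries come from different tables, so strain construction, batch and genotype cannot be told apart in this contrast. For telomere-proximal genes, WT_Ino80 less WT_H2AZ had a median of 0.19, with 52 of 227 higher and 23 lower. There the list had an adjusted p = 0.278, and an adjusted p = 0.675 with an estimated correlation. Lower levels of these genes in H2AZ_4KR thus did not follow the difference between the wild types.

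Leu3, the activator of branched-chain amino acid genes, responds to an intermediate of the leucine pathway that lies upstream of the LEU2 step. In H2AZ_4KR, 4 of 8 Leu3 target genes other than LEU2 fell and 4 did not pass (median -0.72, adjusted p = 9.73e-07, and adjusted p = 0.276 with an estimated correlation). LEU1 stood at 467 ± 44.4 CPM (SD, n = 3) in WT_H2AZ, where LEU2 RNA was not detected, and at 151 ± 7.93, 97.1 ± 27.8 and 107 ± 13.4 CPM in H2AZ_4KR, WT_Ino80 and Ino80_K929R. BAT1, a branched-chain aminotransferase gene, stood at 539 ± 52.3 CPM (SD, n = 3) in WT_H2AZ and at 237 ± 20.2, 193 ± 36.2 and 206 ± 17.5 CPM in the other groups.

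The hypothesis tested was that the presence of LEU2, rather than the mutation, lowers these genes. In all, 6 of 8 targets (GDH1, LEU1, ILV2, LEU4, OAC1 and BAT1) were lower in each of 9 libraries with LEU2 RNA than in each of 3 without, against 764 of 6098 other genes (12.5%). ILV5 and MAE1 were not. ILV5 stood at 718 ± 91.5 CPM (SD, n = 3) in WT_H2AZ and 478 ± 33.1 in H2AZ_4KR, but 861 ± 403 in WT_Ino80 and 827 ± 345 in Ino80_K929R. Its mean was thus lower in H2AZ_4KR alone. MAE1 stood at 49.5 ± 6.64, 58 ± 10.1, 40.3 ± 19.5 and 46.75 ± 19.9 CPM (SD, n = 3) in the same order. The targets are regulated together and were chosen with these libraries in view, so no p is given. The median of the targets in WT_Ino80 less WT_H2AZ, 2 groups without the H2AZ_4KR mutation, was -0.94. A part played by the mutation stays open, since LEU2 and the mutation part the same libraries of the H2AZ table, and another difference between the strains could act on the same genes.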
